A study of Mus musculus with 264 samples.

How the data were processed

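Labelled RNA from 264 two-colour Agilent arrays was analysed, covering 11 mouse strains, 3 tissues (liver, lung, spleen) and 2 treatments (LPS or saline). Per the labels, each of the 66 groups had 2 pools of RNA from 3 mice, described as biological replicates, and each pool was hybridized on 2 arrays, with the sample once in Cy3 and once in Cy5 and a universal mouse reference RNA in the other channel. The deposited values are log2 ratios of the channels made by the authors, already turned so that both dye orientations of a pool point the same way. The log2 scale was read from the range of the values, -18.6 to 17.1. Agilent Feature Extraction is named in the submitters' processing notes, without a version; how the authors corrected the background and normalized the ratios is not given in the sources used here. Deposited array medians lay between -0.295 and 1.11 (median -0.0416). Dye-flip arrays of a pool correlated above 0 in every pool, with a median r of 0.548 across probes as deposited.

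The direction of the ratio is not stated. In the deposited values, those far above 0 recurred between tissues with nearly the same size, which is what a sample channel without signal over a shared reference gives, so the values were read as reference over sample and multiplied by -1. A channel without signal had been given a very small constant, which produced separate groups of values at both ends. The edge of each group was found for each array, in a window of 0.4 between 4.6 and 9.5, as a jump of at least 4 standard units in the density, and values beyond it were moved towards 0 by the value of the edge, as if the small constant had been a larger one (the raised floor). An array without such a jump took the median edge of the others. Where a value beyond the edge lay nearer to the other values of its probe as measured, it was kept, which held for 2.45% of them. After this the median dye-flip r was 0.890 (range 0.566 to 0.964). The raised floor was chosen after the distribution of the values and the spread between pools had been seen, and before any LPS effect was tested. Because the SD of the deposited array medians, 0.1036, was above 0.1, each array was centred on its median, as planned; after the floor was raised the SD was 0.0622. The arrays of a pool were averaged to 1 value. Probes with a value on at least 80% of the arrays of a tissue were tested, which left 19538 in liver, 18059 in lung, 18021 in spleen and 17669 in the joint fit of the tissues. For arrays no count depth exists, and their number limits the precision.

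Group-means models with 22 groups and 44 pools per tissue were fitted in limma 3.58.1 (R 4.3.3, with version 1.17.8 of data.table and version 1.5.0 of statmod), so that all groups of a tissue shared the estimate of the spread between pools. Moderated limma tests were adjusted by Benjamini-Hochberg over all probes of a comparison, and a probe was called at an adjusted p under 0.05. All tests were two-sided. The comparisons were the mean LPS effect of 9 responsive strains, chosen from labels and textbook knowledge, the LPS effect in each strain, in C57(TLR4-/-) and in C3H/HeJ, the difference of the effects of C57(TLR4-/-) and C57/B6, the difference of the mean effect of both Tlr4-deficient strains from that of the 9, and F-tests of equal LPS effects over the 9 strains and of equal saline means over the 11. Tissues were compared in 1 fit of all pools of the 3 tissues. Amplitudes are slopes through 0. Overlaps are given with the number expected if the lists were independent. Pool numbers were checked for pairing: differences between pool 1 and pool 2 of the LPS and saline groups had median correlations across probes of -0.009 in liver, 0.017 in lung and -0.059 in spleen, so no pairing was used. Between tissues the medians were -0.0175 (liver and lung), 0.019 (liver and spleen) and 0.014 (lung and spleen). Of 22 groups, 4, 5 and 8 lay above 0.1, up to 0.325. Whether same-numbered pools of different tissues held the same mice is not stated, and the joint fit treated them as independent.

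The comparisons, tests, filters and most alternatives were chosen before the data were examined. The plan was to test gene means, gene lists (among them Hedgehog pathway genes, targets and transcription factors) and a set of named genes. The files hold probe IDs only, and the mouse gene annotation available (GRCm38.p6) holds none of them, so 0 probes matched a gene. Probes were therefore tested one by one, and the gene lists, with limma camera and fry, and the named genes were not run. Whether the Tlr4 transcript was absent in C57(TLR4-/-) could not be checked either. In place of named genes, 4 probes are given: among those called in all 3 tissues in one direction, the 2 with the largest mean rise and the 2 with the largest mean fall. That rule was set after the files were seen and before the values of any probe were.

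Alternatives were quantile normalization, no centring, arrays of each dye orientation alone, only probes with a value on every array, an adjusted p under 0.01, array weights (limma arrayWeights, whose iteration warned that its tolerance could not be reached), a block for pool number, the 9 strains as replicates, strains of the early or the late array series alone, and leaving out each pool and each strain in turn. Added after the data had been seen were floored values taken as missing, the floor not raised, and the AKR/J pools not used. Other splits of the samples were fitted, 100 drawn with a fixed seed where there were more. The fits were tested on simulated data with the spread of the real pools: of the probes given a 2-fold change, the 9-strain comparison recovered 98.5% in liver, 100% in lung and 100% in spleen, and the comparison within C57(TLR4-/-) 79.1%, 23.9% and 82.1%, with 4 to 9 false calls per tissue. Tables were assembled with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures drawn with matplotlib 3.10.9. The arrays' raw scans were not used here.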

Results

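Gene expression was measured in the liver, lung and spleen of male mice 6 hours after an intraperitoneal injection of bacterial lipopolysaccharide (LPS, 125000 EU per kg) or of saline. The panel held 11 strains. The C57(TLR4-/-) strain lacks Tlr4, the receptor through which mammalian cells sense LPS, and C3H/HeJ carries a spontaneous Tlr4 mutation and is known as hyporesponsive to LPS. The other 9 strains (129/SvIm, A/HeJ, AKR/J, BALB/cJ, C57/B6, DBA/2J, FVB/NJ, LP/J and NZW/LacJ) were treated as LPS-responsive. Each strain contributed 6 LPS and 6 saline mice, whose RNA was combined into pools of 3 animals. Each pool was hybridized on 2 dye-flip arrays against a universal mouse reference RNA, a mixture of RNAs that serves as a common denominator. The series thus comprised 264 arrays in 66 groups of strain, tissue and treatment, with n = 2 pools in every group. The table held 20818 probes, and 19538 were tested in liver, 18059 in lung and 18021 in spleen. A median of 4.01% of the values of an array were missing (range 0.932 to 17.0%). The sample channel was at its floor, without measurable signal, for a median of 3.91% of the values (range 0.315 to 34.4%). The number of arrays limits the precision of every value.

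Changes are given as log2 of LPS over saline, so that a value of 1 is a 2-fold rise. The files do not state which channel is the numerator of the deposited ratio. It was read from the values as reference over sample: values beyond 6.3 on one side recurred between tissues with r of 0.949 to 0.959 across probes, which is what a shared reference would give, against 0.412 to 0.465 on the other side. Were the reading turned, every rise in the text would be a fall and every fall a rise, with the same sizes and p-values. The files pair no probe with a gene, so the Hedgehog pathway and the transcription factors named in the study's title could not be looked up and were not analysed here. Probes are therefore described as groups, and 4 of them are given individually.

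The first comparison asked which transcripts LPS changed in the responsive strains. LPS changed 51.3% of the probes tested in liver and 60.5% of those in spleen. In liver 4005 probes rose and 6017 fell, with median changes of 0.31 and -0.32; with quantile normalization 4668 rose and 4905 fell, so the excess of falls in liver depended mostly on the scaling. In spleen 4298 rose and 6596 fell, with median changes of 0.43 and -0.31. Large changes were more often rises: at 4-fold or more, 166 probes rose and 57 fell in liver, and 149 rose and 36 fell in spleen. The largest rise was 6.83 in liver and 6.3 in spleen, and the largest falls were -3.77 and -4.03. The response at 2-fold or more was shared by the panel. Of the 508 liver probes that rose by this much on average, 493 had a higher mean after LPS in each of the 9 strains, and of the 529 that fell, 506 were lower in each. In spleen these numbers were 711 of 728 and 524 of 543. The probes were chosen on the mean of these same strains, which favours such agreement. The median spread between pools of a group was 0.16 in liver and 0.15 in spleen (SD, log2). The array identifiers fell into an early series (7 of the 9 strains) and a late series (A/HeJ and AKR/J). Within the 7 early-series strains 9170 probes changed in liver and 10183 in spleen, and within the 2 late-series strains 5885 and 8609.

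In lung, LPS changed 4169 probes over the 9 strains, of which 1640 rose and 2529 fell. At 2-fold or more 462 rose and 315 fell, the largest changes being 5.85 and -3.07. The lung pools of AKR/J ran against those of every other strain. Consequently only 23 of the 462 rises and 7 of the 315 falls had one direction in all 9 strains. Without AKR/J, 8400 lung probes changed over the 8 remaining strains: 3494 rose and 4906 fell, at 2-fold or more 577 and 574. Of these 2-fold changes, 557 rises and 554 falls had the same direction in each of the 8. Of the 4169 probes called with AKR/J, 4103 were also called without it, and 4099 kept their direction. The median spread between pools was 0.36 with AKR/J and 0.19 without it (SD, log2). Within the early-series strains 4229 lung probes changed, and within A/HeJ and AKR/J together 159. Both counts used the larger spread of the fit with the AKR/J pools, so they cannot be set beside the 8400.

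The position of each pool along the response of the other strains separated the treatments almost completely (plot of pool scores). The score was the slope of a pool's deviation from the mean of its strain's 4 pools on the mean LPS change of the other strains. In 128 pools the score was above 0 after LPS and below 0 after saline, and the 4 exceptions were the AKR/J lung pools. There, LPS pool 1 scored -0.256, LPS pool 2 -0.402, saline pool 1 0.609 and saline pool 2 0.0422. In the remaining pools of the 9 strains, LPS scores lay between 0.328 and 0.727 and saline scores between -0.795 and -0.133. The sample channel of the AKR/J lung arrays was at its floor for 3.12 to 34.4% of the values.

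**Figure D1:**
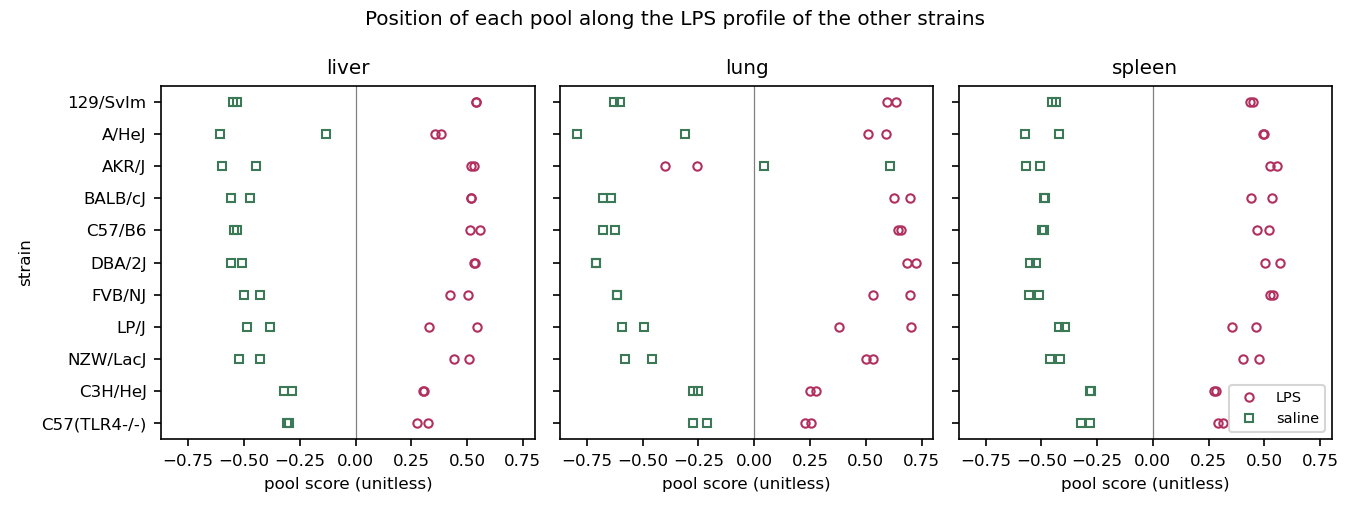
Position of each pool along the LPS profile of the other strains (x axis, slope, unitless) for each strain (y axis) in liver, lung and spleen; circles are LPS pools and squares saline pools, 2 of each per strain. In 128 pools the sign of the score goes with the treatment, and the 4 exceptions are the AKR/J lung pools.

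The 3 tissues were compared to find which part of the response they shared. A core of 178 probes rose 2-fold or more in liver, lung and spleen alike, where independence of the tissues would give 0.510, and 28 probes fell by as much in all 3 (0.254 by independence). At any size, 828 probes rose in all 3 tissues (85.0 by independence) and 1190 fell (294). The lung lists include AKR/J. Pairs of tissues shared more rises than falls among the 2-fold changes. Liver and lung shared 232 rises and 63 falls, liver and spleen 227 and 90, and lung and spleen 254 and 107, where independence would give 12.5 and 8.39, 19.9 and 15.1, and 18.3 and 8.97. Without AKR/J in lung, liver and lung shared 262 rises and 100 falls, lung and spleen 291 and 171, and all 3 tissues 191 and 39. Called changes in opposite directions were fewer than by independence: 360 against 1059 for liver and lung, 2081 against 2801 for liver and spleen, and 365 against 1187 for lung and spleen. Across the 17632 probes tested in every tissue, the changes correlated with r = 0.58 for liver and lung, 0.45 for liver and spleen and 0.62 for lung and spleen; probes are not independent replicates.

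Other parts of the response were stronger in a single tissue. In a joint fit of the 3 tissues, the LPS change differed between lung and liver for 5013 of 17669 probes (2636 higher in lung), between spleen and liver for 6824 (3603 higher in spleen) and between spleen and lung for 5251 (2839 higher in spleen). With quantile normalization the share higher in spleen fell from 52.8 to 48.1% against liver and from 54.1 to 48.8% against lung, so which tissue had the higher change more often depended on the scaling. With the 9 strains as replicates, 2725 probes differed between lung and liver and 2958 between spleen and lung. Of the probes that rose 2-fold or more in liver, 246 of 488 rose by more there than in both other tissues, and of those that fell, 367 of 504 fell by more. For spleen these numbers were 451 of 719 and 345 of 535, and for lung 154 of 450 and 133 of 300. The lung means included AKR/J, whose opposite changes made them smaller. These numbers were not computed without it, so the lung numbers cannot be ranked against those of liver and spleen. Without the AKR/J pools, the counts of differing probes were 7781 for lung against liver, 8795 for spleen against liver and 8849 for spleen against lung.

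Each strain was then examined on its own, with 2 LPS pools against 2 saline pools. In liver the number of probes that changed ranged from 3367 in A/HeJ to 5630 in AKR/J (median 4498), and in spleen from 4400 in NZW/LacJ to 7897 in AKR/J (median 5650). In lung it ranged from 458 in LP/J to 2311 in A/HeJ (median 726), and without AKR/J in the fit, which lowered the shared estimate of the spread, from 2471 in LP/J to 8628 in A/HeJ. The next highest count was then 4429 in NZW/LacJ. The 2 lung saline pools of A/HeJ were unlike each other (pool scores -0.310 and -0.795). Whether 1 of them accounts for its count was not tested.

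The amplitude of a strain's response was taken as the slope of its LPS changes on the mean changes of the other strains of the 9, over the probes that changed 2-fold or more in those, so that 1 is a response as strong as the others' (plot of amplitudes). In liver the 9 strains had amplitudes from 0.740 ± 0.275 in A/HeJ to 1.08 ± 0.00981 in 129/SvIm (SD over the 4 pairings of an LPS with a saline pool), with a mean of 0.977 ± 0.115 (SD, n = 9 strains). In spleen they lay between 0.817 ± 0.0657 in LP/J and 1.08 ± 0.0402 in AKR/J, with a mean of 0.972 ± 0.0945 (SD, n = 9 strains). In lung the amplitude of AKR/J was -0.666 ± 0.334, while the others lay between 1.04 ± 0.0724 in NZW/LacJ and 1.42 ± 0.0223 in DBA/2J. With AKR/J left out of the reference mean as well, the 8 lung amplitudes lay between 0.851 and 1.12.

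**Figure D2:**
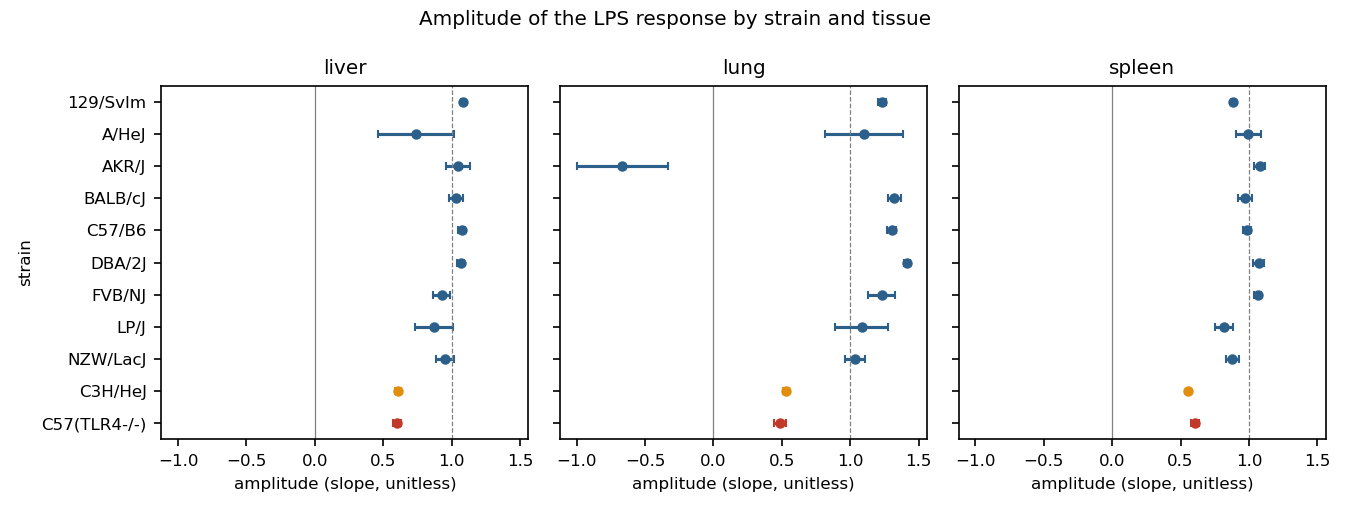
Amplitude of the LPS response (x axis, slope, unitless) of each strain (y axis) in liver, lung and spleen; points are the slope over both pools and bars the SD over the 4 pairings of an LPS with a saline pool. C57(TLR4-/-) and C3H/HeJ lie between 0.485 and 0.608 in the 3 tissues, and AKR/J lies at -0.666 in lung.

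The next comparison asked how much of the response required functional Tlr4. Probes also differed between LPS and saline pools of the strains without it. In C57(TLR4-/-), 2306 probes changed in liver (903 rose, 1403 fell), 122 in lung (92 rose, 30 fell) and 5682 in spleen (2537 rose, 3145 fell); with quantile normalization 51.5% of the spleen changes were rises instead of 44.6%. In C3H/HeJ, 5159 changed in liver (2225 rose, 2934 fell), 43 in lung, of which 40 rose, and 2510 in spleen (1562 rose, 948 fell). Without the AKR/J pools in the fit, the lung counts were 752 and 298. Single pools weighed on these counts: without its saline pool 2, C57(TLR4-/-) had 1022 changed probes in liver, and without its LPS pool 1, C3H/HeJ had 2672. Over the probes changed 2-fold or more in the 9 strains, the changes followed their profile at a reduced size (scatter of the changes). Across all probes the correlation with the 9-strain mean was weaker, between 0.49 and 0.74. In the liver of C3H/HeJ, 1285 rises and 2207 falls were shared with the 9 strains, and 244 called changes went the other way. In the spleen of C57(TLR4-/-), 1725 rises and 2337 falls were shared, and 355 went the other way. The liver count of C3H/HeJ lay above that of every responsive strain but AKR/J. The amplitude of C57(TLR4-/-) was 0.603 ± 0.0289 in liver, 0.485 ± 0.0415 in lung and 0.607 ± 0.0272 in spleen, and that of C3H/HeJ was 0.608 ± 0.0212, 0.529 ± 0.0204 and 0.558 ± 0.00694 (SD over the 4 pairings). Every one of these lay below the lowest of the 9 strains in liver and spleen, although the pairings of A/HeJ in liver spread from 0.489 to 0.992, and with the floor not raised C3H/HeJ in liver (0.615) no longer lay below the lowest of the 9 (0.605). In lung the 2 amplitudes lay below every strain but AKR/J, and at 0.388 and 0.411 once AKR/J was left out.

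Among the probes that changed 2-fold or more in the 9 strains (1037 in liver, 777 in lung, 1271 in spleen), C57(TLR4-/-) had the same sign for 95.5%, 87.0% and 95.8%, and C3H/HeJ for 93.7%, 90.1% and 96.2%. Of these probes, 606 in liver, 42 in lung and 994 in spleen were called in the same direction in C57(TLR4-/-), and 671, 34 and 895 in C3H/HeJ. Without AKR/J in the lung fit, 203 of 577 rises and 46 of 574 falls were called in C57(TLR4-/-), and 162 and 22 in C3H/HeJ. The median ratio of the change in C57(TLR4-/-) to that in the 9 strains was 0.56 for rising and 0.64 for falling probes in liver, 0.49 and 0.30 in lung, and 0.62 and 0.55 in spleen. In C3H/HeJ the ratios were 0.54 and 0.70 in liver, 0.49 and 0.27 in lung, and 0.62 and 0.40 in spleen. Without AKR/J in the lung fit, the lung ratios were 0.39 and 0.23 in C57(TLR4-/-), and 0.39 and 0.22 in C3H/HeJ. Of the 178 probes that rose 2-fold or more in all 3 tissues, 109 were called as rising in the liver and 155 in the spleen of C57(TLR4-/-), and 112 and 159 in C3H/HeJ; in lung the numbers were 14 and 13.

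**Figure D3:**
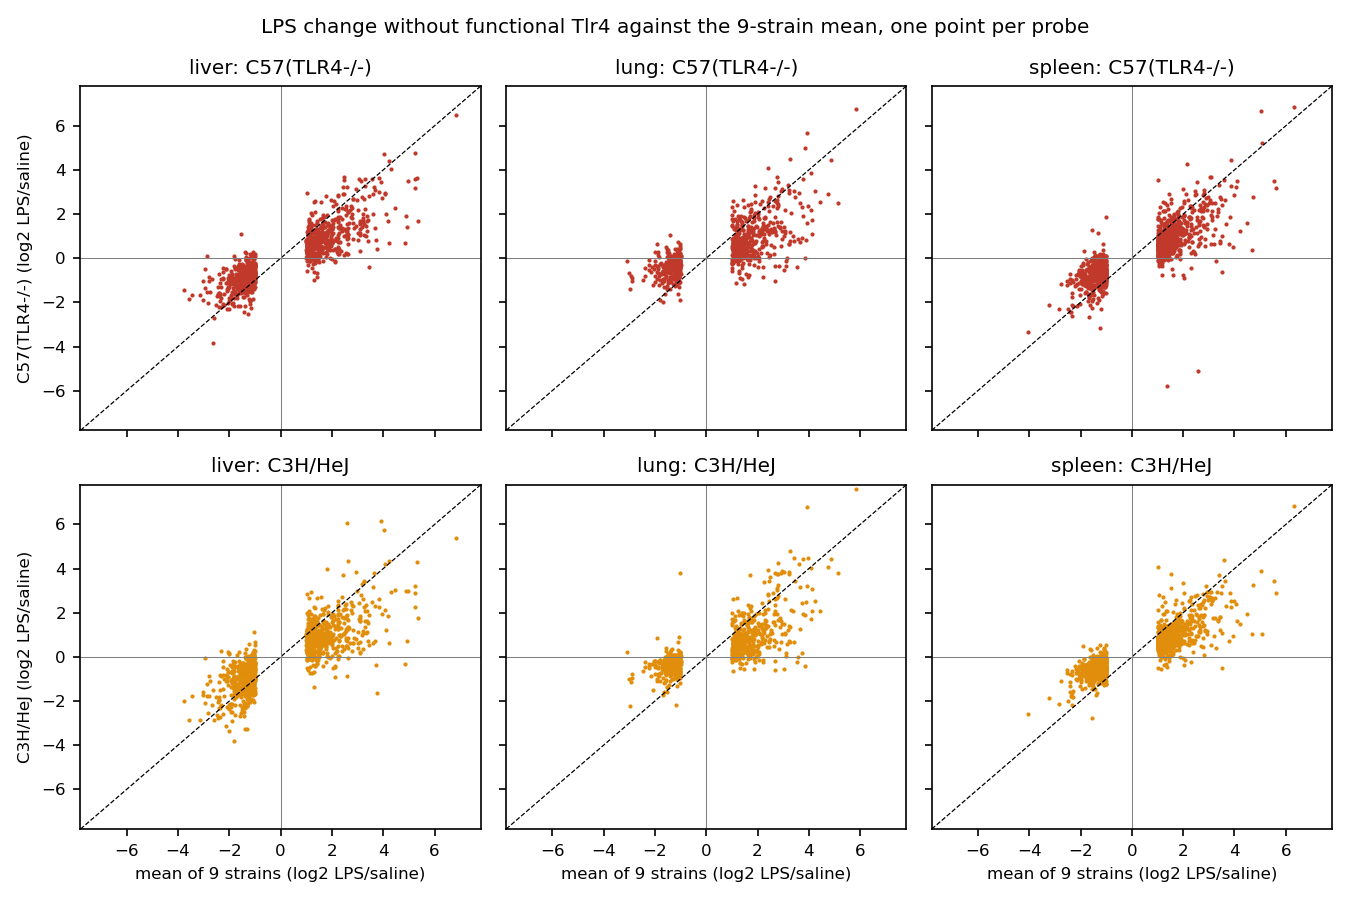
LPS change in C57(TLR4-/-) (upper panels) and C3H/HeJ (lower panels) on the y axis against the mean change of the 9 strains on the x axis (both log2 LPS/saline), 1 point per probe changed 2-fold or more in that mean. In liver the points correlate with r = 0.875 and 0.828, in lung with 0.730 and 0.747 and in spleen with 0.835 and 0.869, most of them nearer to 0 than the dashed line of equal change.

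The difference from the responsive strains was tested directly. The mean change of the 2 strains without functional Tlr4 differed from that of the 9 strains for 2554 probes in liver (1519 higher, 1035 lower), 196 in lung (96 higher, 100 lower) and 4126 in spleen (2323 higher, 1803 lower). Which direction was the more frequent depended on the scaling in liver (59.5% higher, 49.5% with quantile normalization) and lung (49.0% and 52.3%). Without AKR/J 3135 lung probes differed. C57(TLR4-/-) alone differed from C57/B6, the strain of the same named background, for 677 probes in liver (420 higher, 257 lower), 31 in lung (11 higher, 20 lower) and 4017 in spleen (1859 higher, 2158 lower). The share that was higher was 46.3% in spleen, but 51.2% with quantile normalization and 51.5% without centring, and in lung 35.5%, but 50% with quantile normalization. Without AKR/J in the fit, 1144 lung probes differed between these strains. The arrays of C57(TLR4-/-) belonged to the late series and those of C57/B6 to the early one, so in this comparison series and genotype cannot be told apart. Against the 2 late-series strains, C57(TLR4-/-) differed for 762 probes in liver, 105 in lung and 3871 in spleen. Against the 7 early-series strains C3H/HeJ differed for 2675, 56 and 2051. The lung count of 105 rests on the mean of A/HeJ and the opposing AKR/J, so it does not measure the difference within the series. Both lung counts used the larger spread of the fit with the AKR/J pools.

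Strain differences were assessed with limma F-tests. The LPS change differed among the 9 strains for 2005 probes in liver, 1173 in lung and 6803 in spleen, and for 1476 lung probes without AKR/J. The lung count of 1173 was not stable: it was higher with quantile normalization, with array weights and without some single AKR/J pools. In saline pools, the level differed among the 11 strains for 14781 probes in liver, 10481 in lung and 14766 in spleen. The lung count was 5473 without AKR/J saline pool 2 and 10251 without all AKR/J pools. Within the 8 early-series strains alone, the saline level differed for 9910, 5121 and 10070 probes.

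Among the probes that changed in one direction in all 3 tissues, those with the largest mean rise and the largest mean fall are given individually (plot of the 4 probes); all changes are means over strains with the SD over the 9 strains. A_51_P337308 rose by 2.63 ± 1.61 in liver (adjusted p = 2.48e-06, 9 of 9 strains), 5.85 ± 5.29 in lung (adjusted p = 2.23e-08, 8 of 9) and 6.3 ± 1.03 in spleen (adjusted p = 2.11e-17, 9 of 9). In spleen it also rose in the strains without functional Tlr4, by 6.86 in C57(TLR4-/-) (adjusted p = 3.16e-07) and 6.84 in C3H/HeJ (adjusted p = 7.18e-07). The difference of both from the 9 strains was 0.54 there, with adjusted p = 0.603. The probe was at the floor on 6 of 36 saline arrays of the 9 strains in spleen, so its rise there is limited by the floor. In liver its change was 1.08 in C57(TLR4-/-) (adjusted p = 0.693) and 4.35 in C3H/HeJ (adjusted p = 0.00814), and in lung 6.74 (adjusted p = 0.103) and 7.59 (adjusted p = 0.0914). In liver its mean level in the 9 strains after LPS, 6.02 (log2 sample over reference), was near the edge for the reference channel (median 6.55). Arrays with the reference at its floor were not counted for this probe. A_51_P386214 rose by 5.37 ± 1.51 in liver (adjusted p = 3.25e-20, 9 of 9 strains), 4.11 ± 2.92 in lung (adjusted p = 6.61e-12, 8 of 9) and 4.20 ± 0.97 in spleen (adjusted p = 5.83e-22, 9 of 9). Its rise was smaller without functional Tlr4: 1.68 in C57(TLR4-/-) and 1.76 in C3H/HeJ in liver, and 1.25 and 1.48 in spleen. In liver, however, the responsive strain A/HeJ rose by only 1.41. The 2 liver saline pools of A/HeJ were unlike each other (pool scores -0.608 and -0.133), so that value may rest on 1 of them. The difference of both strains without functional Tlr4 from the 9 strains was -3.65 in liver (adjusted p = 6.17e-08) and -2.83 in spleen (adjusted p = 7.21e-09). In lung its changes were 1.75 (adjusted p = 0.914) and 2.07 (adjusted p = 1), and the difference of -2.20 did not pass (adjusted p = 0.0987).

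The falling probe A_51_P389988 changed by -3.56 ± 0.40 in liver (adjusted p = 1.33e-18, 9 of 9 strains), -0.70 ± 0.98 in lung (adjusted p = 0.00148, 8 of 9) and -4.03 ± 0.66 in spleen (adjusted p = 1.61e-27, 9 of 9). It also fell in C57(TLR4-/-), to -1.84 in liver and -3.35 in spleen, and in C3H/HeJ, to -2.85 and -2.59, the difference of both from the 9 strains being 1.21 (adjusted p = 0.0023) and 1.06 (adjusted p = 4.52e-07). In their lungs the changes were 0.03 and -0.01, and the difference from the 9 strains, 0.71, did not pass (adjusted p = 0.745), so a fall there is not excluded. A_51_P456280 changed by -2.40 ± 0.73 in liver (adjusted p = 4.94e-14, 9 of 9 strains), -2.13 ± 1.18 in lung (adjusted p = 4.00e-12, 8 of 9) and -2.34 ± 0.23 in spleen (adjusted p = 1.59e-21, 9 of 9). Its spleen value was -0.98 in C57(TLR4-/-) (adjusted p = 0.000258) and -0.63 in C3H/HeJ (adjusted p = 0.0224). In liver these strains had -1.69 (adjusted p = 0.00601) and -1.16 (adjusted p = 0.0371), and in lung -0.42 and -0.34, neither of which passed. The difference of both from the 9 strains was 0.97 in liver (adjusted p = 0.043), 1.75 in lung (adjusted p = 0.0034) and 1.53 in spleen (adjusted p = 2.39e-08). After LPS this probe was at the floor on 22 of 36 arrays in liver, 17 in lung and 19 in spleen, so its falls are bounded by the floor. For each of the 4 probes AKR/J was the strain of opposite sign in lung, with changes of -7.32 for A_51_P337308, -3.57 for A_51_P386214, 1.15 for A_51_P389988 and 0.75 for A_51_P456280.

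**Figure D4:**
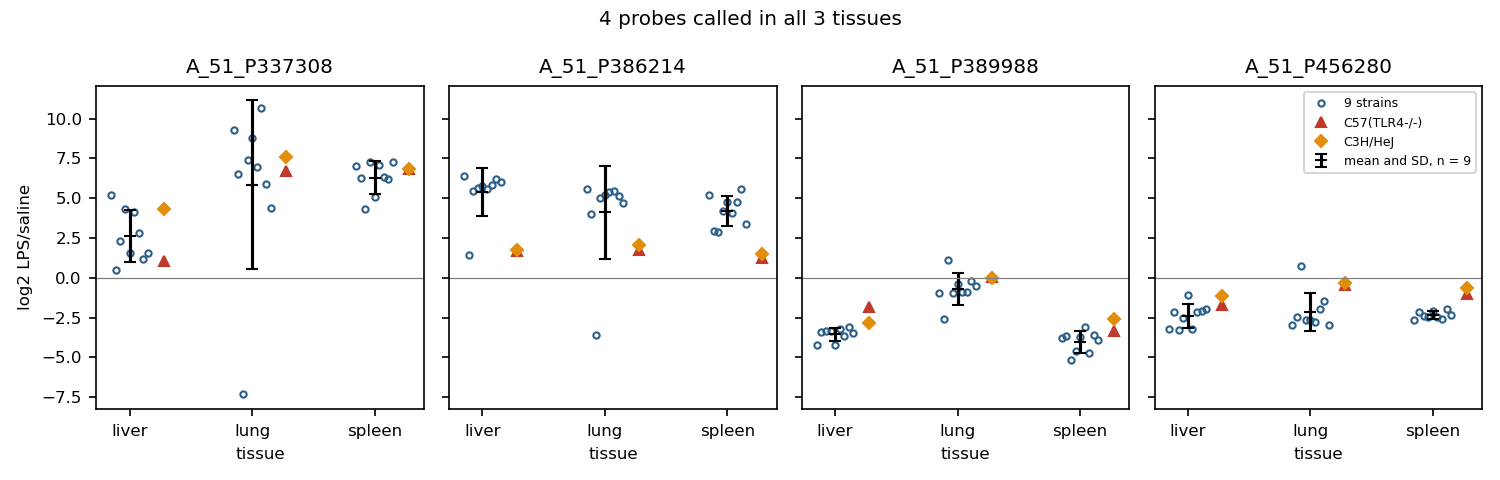
LPS change (y axis, log2 LPS/saline) of 4 probes in liver, lung and spleen (x axis); open circles are the 9 strains, bars their mean and SD, triangles C57(TLR4-/-) and diamonds C3H/HeJ. A_51_P337308 rises to 6.86 and 6.84 in the spleen of the strains without functional Tlr4, against 1.25 and 1.48 for A_51_P386214.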

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

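The tests of a mislabelled AKR/J lung sample and of an array batch behind the response without functional Tlr4, the tests of admixed RNA of strains other than A/HeJ, by strain-marking probes and with the ratio read the other way, the pairs of responding strains set beside the strains without functional Tlr4, and the fits without AKR/J, were chosen only after the result was seen. The bounds first set for a mislabelled sample, a mixed sample in liver and a response without functional Tlr4 proved too weak and were made stricter after the result was seen.

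Among 18 groups of 9 strains searched for a strain lying far from the rest, 6 held one, where chance gives about 1 in 20 groups. AKR/J stood apart in lung in its amplitude, -0.666 against 1.04 for the next strain, and in its changes of A_51_P337308 (-7.32), A_51_P386214 (-3.57) and A_51_P456280 (0.75). A/HeJ stood apart in liver with a rise of A_51_P386214 of 1.41, the next lowest being 5.47, and in lung with 2311 changed probes, the next highest being 921. The saline pools of A/HeJ were unlike each other in both tissues. Their pool scores were -0.608 and -0.133 in liver, and -0.310 and -0.795 in lung. Whether a single pool accounts for the A/HeJ values was not tested.

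The lung response of AKR/J ran opposite to that of the other strains. Weak hybridization alone is argued against, since the amplitude was still -0.617 with floored values missing. A mislabelled sample cannot be told apart: saline pool 1 minus LPS pool 2 correlated across probes with the LPS profile of the other 8 strains at r = 0.920 (0.867 to 0.971 for LPS minus saline in those strains), but these are the pools that raised the question, and LPS minus saline in the other 3 pairings gave -0.662, -0.510 and -0.549. By 166 strain-marking probes, 38 of the 44 lung pools were nearest to their own strain. A/HeJ saline pool 2 was nearest to C57(TLR4-/-) (r = 0.557, against 0.304 with A/HeJ). RNA of another strain cannot be told apart for AKR/J LPS pool 1 and saline pool 2, since by these probes 2 of the 4 AKR/J pools (LPS pool 2, r = 0.607, and saline pool 1, r = 0.563) were nearest to AKR/J, while these others matched no strain above r = 0.202 and had 10.6 to 34.4% of their sample values at the floor. A lung-specific property of the strain also stays open, with nothing in the design to test it, although its amplitude in spleen was 1.08.

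These pools also decide whether chance can be excluded in lung. Over the 9 strains, 10 of 100 splits of the pools within strains called as many lung probes as the real one (4169), with up to 9032, and each of those others exchanged AKR/J pools between the treatments. Without AKR/J, 1 of 100 splits, the real one, reached 8400, the highest other being 5545. In liver and spleen, 1 of 100 splits, again the real one, reached 10022 and 10894, with 4120 and 5964 as the highest others, so chance can be excluded there.

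The LPS response differed between the strains without functional Tlr4 and the 9 strains for 2554 probes in liver, 196 in lung and 4126 in spleen. Of the 55 choices of 2 strains, 1, the real one, called as many in liver (highest other 1483). That is the fewest this test can give. It met the bound set beforehand on the share of such choices, so chance is argued against there. In spleen 2 did (highest other 4452), which also met that bound. Another choice called more than the real one there, so chance is not taken as excluded in spleen. In lung 16 did (highest other 2419), so chance cannot be excluded in lung. The spleen choice that exceeded the real one joined A/HeJ and AKR/J, both of the late array series, but AKR/J with FVB/NJ (4023) and C57/B6 with DBA/2J (3971) came close to the real one, so pairs of responding strains can differ on nearly as many spleen probes. Within a series, 3871 spleen probes differed for C57(TLR4-/-) and 2051 for C3H/HeJ. Without AKR/J, 2 of 45 choices called as many as the 3135 lung probes, the highest other, 4759, being A/HeJ with NZW/LacJ. Between C57(TLR4-/-) and C57/B6 the response differed for 677 probes in liver, 31 in lung and 4017 in spleen.

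Both strains without functional Tlr4 kept part of the response. An array batch is argued against, because the lowest correlation with the 9-strain profile across the probes changed 2-fold or more was 0.730 (0.491 across all probes) and the arrays of these strains belong to different series. Admixed RNA of responding mice would give the same share from falling and from strongly rising probes, but the first was 2.75 and 3.44 times the second in liver (lowest pairing 1.98, against at most 1.16 in 8 of the responding strains) and 1.80 and 1.66 times in spleen (C57(TLR4-/-) and C3H/HeJ). The bound of 1.5 set beforehand was wrong for A/HeJ, which itself had 3.15 in liver (1.32 to 11.1 over its pairings), and in spleen AKR/J had 1.74 (median of the 9 strains 0.957). Were the ratio read the other way, the values in liver, 3.09 and 2.25, would rest on 6 strongly rising probes and LP/J would have 2.27. In spleen the values would be 1.47 and 2.31, resting on 2 such probes, and DBA/2J would have 2.26. A mixed sample therefore cannot be told apart in either tissue. Strain-marking probes did not help, as 0 of the 9 strains had the 30 asked for. What remained in each strain after the 9-strain profile was removed correlated across probes at r = 0.518 in liver and 0.448 in spleen, where 36 pairs of responding strains treated alike had medians of 0.147 and 0.180, but 1 and 3 of them were as high, up to 0.541 and 0.555 (in lung without AKR/J 0.707 against at most 0.435), so a response that does not pass through Tlr4 cannot be told apart.

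The response differed among the 9 strains for 2005 probes in liver, 1173 in lung and 6803 in spleen. Between tissues it differed for 5013 probes in lung against liver, 6824 in spleen against liver and 5251 in spleen against lung. Of 100 exchanges of tissue labels within strains, 1, the real assignment, called as many in each comparison, with 4059, 5712 and 4276 as the highest others, so chance can be excluded.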

How the results depend on the processing

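Floored values taken as missing, the floor not raised, and the AKR/J pools not used were chosen after the data had been seen; the other settings were planned. Of the comparisons of a main count or amplitude with a setting, 302 stayed within 1.5 times the count or within the spread of the amplitude, 105 moved further and 1 changed sign: without AKR/J the lowest lung amplitude was 0.851. None of the 27 counts moved without centring. Under the settings in which the 4 probes were refitted, no 9-strain call of them was lost but that of A_51_P389988 in lung with the floor not raised (-0.69). Their calls in other comparisons were not followed. The count for the 9 strains moved in spleen under no setting and in liver under 1, the 2 late-series strains alone. Gene lists, named genes and gene means were not run, since no probe was paired with a gene. No scaling shifted the median change by more than 0.045. Signal over background limits probes at the floor, whose changes are bounds, and simulated 2-fold changes were found for 23.9% of probes within C57(TLR4-/-) in lung. Except where a sentence names a cause, the cause was not tested.

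With fewer strains, the late series alone called 5885 probes over its 2 strains in liver and 159 in lung, where AKR/J opposed A/HeJ. C57(TLR4-/-) differed from those strains for 762 probes in liver and 105 in lung, and C3H/HeJ from the 7 early-series strains for 56 in lung and 2051 in spleen. These lung counts kept the AKR/J pools in the fit. Without the AKR/J pools, which lowered the spread, lung gave 8400 probes for the response of the 8 remaining strains, 752 for C57(TLR4-/-), 298 for C3H/HeJ, 1144 for C57(TLR4-/-) against C57/B6, 3135 for both against the rest, and a median of 3420.5 per strain. Amplitudes were then 0.388, 0.411 and at most 1.12, and tissue differences 7781 for lung against liver and 8849 for spleen against lung.

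With an adjusted p under 0.01, a stricter threshold by construction, liver gave 1276 probes for C57(TLR4-/-), 2808 for C3H/HeJ, 235 for the former against C57/B6, 1272 for both against the rest and 732 for strain differences. Lung gave 61, 20, 16, 76 and 666 in that order, 341 for the median strain and 6799 for saline; spleen gave 3541, 1537, 2170, 2724 and 4082. On Cy3 arrays alone, C57(TLR4-/-) had 1453 probes in liver and 64 in lung, and C3H/HeJ 25 in lung and 1637 in spleen, with amplitudes of 0.544 for C3H/HeJ in spleen and at most 1.38 in lung. On Cy5 arrays alone, liver gave 1362, 1936, 261 and 1195 for C57(TLR4-/-), C3H/HeJ, C57(TLR4-/-) against C57/B6 and both against the rest, lung 78 for the first and 115 for the last, and the C3H/HeJ spleen amplitude was 0.567. Probes with a value on every array gave 78 for C57(TLR4-/-) in lung.

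With quantile normalization, lung gave 6555 probes for the 9 strains, 196 for C57(TLR4-/-), 171 for C3H/HeJ, 466 for C57(TLR4-/-) against C57/B6, of which 50% were higher against 35.5% in the report, 1006 for both against the rest, 2383 for the median strain and 2713 for strain differences. Its amplitudes were 0.555 for C3H/HeJ and at most 1.09 in liver, 0.409 for C57(TLR4-/-) and at most 1.38 in lung, and 0.526, 0.583 and at most 1.12 in spleen. Array weights gave 2454, 950, 2434, 1365 and 788 in lung for the 9 strains, C57(TLR4-/-), C3H/HeJ, C57(TLR4-/-) against C57/B6 and both against the rest, 3747 for the median strain and 2622 for strain differences, 3220 for C57(TLR4-/-) and 4633 for C3H/HeJ in spleen, and 1611 and 1757 for lung against liver and spleen against lung. A replicate block by pool number had little ground over all groups (correlation 0.0153 across tissues), though a single group reached 0.325 between liver and lung. This block gave 1104 for strain differences in liver. In lung it gave 51, 7, 16 and 61 for the comparisons of C57(TLR4-/-), C3H/HeJ, the former against C57/B6 and both against the rest, 353 for the median strain and 519 for strain differences. The 9 strains as replicates gave tissue differences of 2725 for lung against liver and 2958 for spleen against lung.

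With the floor not raised, lung gave 2619 probes for the 9 strains, 230 for C57(TLR4-/-), 12 for C3H/HeJ, 86 for C57(TLR4-/-) against C57/B6 and 357 for the median strain, and tissue differences were 3340, 4457 and 3365. Amplitudes were then 0.432 for C57(TLR4-/-), 0.615 for C3H/HeJ and 0.605 to 1.01 for the 9 strains in liver, 0.397, 0.445 for C3H/HeJ and at most 1.24 in lung, and 0.526, 0.447 and 0.696 to 1.27 in spleen. Floored values missing gave 76 for C57(TLR4-/-) against C57/B6 in lung and at most 1.10 in liver. Amplitudes over probes with no fold minimum were 0.465 for C3H/HeJ and at most 1.37 in lung, and 0.534 and at most 1.18 in spleen.

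Each pool was also left out in turn, a lone pool being assumed to vary like the other groups. In liver, C57(TLR4-/-) then had 1022 to 2526 probes (1027 without its LPS pool 1, 1530 and 1022 without saline pools 1 and 2), C3H/HeJ 2672 to 5423 (2672 without its LPS pool 1, 3388 and 2824 without saline pools 1 and 2), C57(TLR4-/-) against C57/B6 343 to 844 (343, 378 and 374 without LPS pool 1, saline pool 1 and saline pool 2 of the former), both against the rest 1645 to 2750 (lowest without C57(TLR4-/-) LPS pool 1) and strain differences 1601 to 3058 (highest without A/HeJ saline pool 1), while the highest amplitude was 1.05 to 1.12. In spleen, C57(TLR4-/-) had 3448 to 6053 (lowest without its LPS pool 1), C3H/HeJ 1446 to 2731 (1458, 1530 and 1446 without LPS pool 1, LPS pool 2 and saline pool 2) and C57(TLR4-/-) against C57/B6 2614 to 4363 (2614 and 2671 without LPS pool 2 and saline pool 2 of C57/B6). In lung, the 9 strains had 3768 to 6420 (highest without AKR/J LPS pool 2) and C57(TLR4-/-) 54 to 221 (54 and 67 without its LPS pool 2 and saline pool 1, 207 to 221 without any AKR/J pool in turn). C3H/HeJ had 2 to 87 in lung (2, 11, 9 and 3 without its LPS pools 1 and 2 and saline pools 1 and 2, 81 to 87 without an AKR/J pool), and C57(TLR4-/-) against C57/B6 17 to 203 (17 and 20 without LPS pool 1 and saline pool 2 of C57/B6, 116 to 203 without an AKR/J pool). Both against the rest had 82 to 962 in lung (82 to 110 without any C3H/HeJ pool, 98 to 109 without LPS pool 1 or 2 or saline pool 2 of C57(TLR4-/-), 326 to 962 without an AKR/J pool), and the median strain 581 to 1743 (1743, 1717 and 1108 without AKR/J LPS pools 1 and 2 and saline pool 2). Strain differences in lung were 983 to 8517 (8517, 1979 and 1792 without AKR/J LPS pools 1 and 2 and saline pool 1) and saline differences 5473 to 13886 (lowest without AKR/J saline pool 2); lung amplitudes were 0.480 to 0.545 for C3H/HeJ and at most 1.33 to 1.46. Spleen against lung gave 5056 to 8116 (highest without AKR/J LPS pool 2). Without each strain in turn, the lung response had 3457 to 8400 probes, lung against liver 4310 to 7781 and spleen against lung 4683 to 8849, each highest without AKR/J.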

Other observations

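The reading of the probes of one tissue in another tissue was chosen only after the result was seen, and 8 strains were asked for in lung because AKR/J was known to run the other way there; the other tests were not. Passing after adjustment was asked for only after the result was seen. Probes typical of a tissue were defined in the saline pools of C57(TLR4-/-) and C3H/HeJ alone, as those at least 8-fold higher than in both other tissues, and their LPS changes were read in the 9 strains, whose pools had no part in the choice. Of 257 liver-enriched probes, 178 fell in liver after LPS and 29 rose, against 30.8% falling and 20.5% rising among all probes. Their median change was below 0 in 9 of 9 strains, with a mean of -0.41 ± 0.13 (SD, n = 9 strains; exact sign test, p = 0.00391, adjusted p = 0.0117 over 9 such tests). Of 150 lung-enriched probes, 77 fell in lung and 8 rose, and the median was below 0 in 8 of 9 strains, AKR/J being the exception (exact sign test, p = 0.0391, adjusted p = 0.0586). Of 85 spleen-enriched probes, 54 fell in spleen and 13 rose, and the median was below 0 in 8 of 9 strains, LP/J being the exception (exact sign test, p = 0.0391, adjusted p = 0.0586). The hypothesis that LPS lowers the transcripts typical of an organ was met in liver; in lung and spleen the sign test did not pass after adjustment. Were the ratio read the other way, these would be probes at least 8-fold lower in their tissue, and their falls would be rises. Fewer cells of the main type, or less transcription in them, may each lower the median in 9 of 9 strains, and neither was tested.

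The probes of one tissue were also read in the others. Of the 85 spleen-enriched probes, 35 rose in lung after LPS and 4 fell, against 9.08% rising and 14.0% falling among all lung probes. The median change was above 0 in 8 of 9 strains (exact sign test, p = 0.0391, adjusted p = 0.0586). In liver 21 of these probes rose and 14 fell. Lung-enriched probes in spleen went the other way, with 83 of 150 falling and 28 rising, and the median below 0 in 9 of 9 strains (exact sign test, p = 0.00391, adjusted p = 0.0117). Liver-enriched probes in spleen also had a median below 0 in 9 of 9 strains (exact sign test, p = 0.00391, adjusted p = 0.0117), but with a mean of only -0.06, and 33.1% of them fell there against 36.6% of all probes.

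Saline levels differed between the strains on most probes in liver and spleen, and in lung on 10481 of 18059, but on 5473 without AKR/J saline pool 2. The array series may account for a part: C57(TLR4-/-) was nearest to C57/B6 in 0 of 3 tissues and nearest to another late-series strain in each, AKR/J in liver and A/HeJ in lung and spleen. Series alone is argued against as the whole cause, since within the 8 early-series strains 28.4% of the probes still differed in lung, 50.7% in liver and 55.9% in spleen. A part may follow the strains themselves: among those strains, the best match of a saline profile in another tissue was the same strain in 34 of 48 comparisons (70.8%, where chance gives 12.5%). The correlations behind these matches were weak, with a median r of 0.172 for the same strain (lowest -0.141). Each pair of tissues was read both ways, so the comparisons are not independent. Sequence variants under the probes stay open and were not tested, as probe sequences were not used here.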
